A study of Oryzias latipes with 18 samples.

How the data were processed

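Whole brains of adult medaka (Oryzias latipes, strain Cab), a small freshwater fish, were profiled by RNA sequencing in 18 libraries. The libraries fall into 6 groups of 3, by genotype (wild type, oxt I22F/I22F or oxtr1-/-) and sex, and each library pooled 2 brains. The sample labels give whole brain as the tissue, while the series title names brain and pituitary, so the files alone do not say how much pituitary each sample held. Per the labels, ribosomal RNA was removed with Ribo-Zero Gold and strand-specific libraries were made with a TruSeq kit.

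The deposited files hold raw read counts per Ensembl gene, 1 file per library, with no normalisation and no filter. Per the file headers, the authors made these counts with featureCounts 1.5.3 over the exons of Ensembl annotation release 94. The labels also name Bowtie2 and HISAT2, without saying what each did. The counting options gave every read to each gene it overlaps and set no strand, although the kit keeps it. A read in exon bases that genes share, on the same or opposite strands, therefore counts for each of them. This holds for at least part of the exon bases of 4966 genes. The headers name no option for read pairs.

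The files name genes by Ensembl identifier. Symbols were added by position from a RefSeq gene table of the same assembly, where both spans overlapped by at least 0.5 of their union, or where an otherwise unmatched pair covered at least 90% of the shorter span. Of 24365 genes, 18236 (74.8%) were matched, 9247 of them to a proper symbol. The RefSeq table gives no strand, so a match rests on position alone. It lists isotocin and oxytocin as synonyms of LOC101160739 and vasotocin as a synonym of the gene it calls oxt, and these synonyms were followed. The gene named oxtr1 in the labels was taken to be itr1, and oxtr (synonym itr2) to be the other oxytocin receptor.

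Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation and the filterByExpr filter by group (minimum count 10, minimum total 15), which left 18723 genes. All 18 libraries were fitted in 1 model with 6 group means and no block. The 12 comparisons were each mutant against wild type in females, in males and averaged over the sexes, both mutants against each other, males against females in each genotype, and the difference of each mutant effect between the sexes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM on TMM-scaled library sizes, given as mean ± SD with n = 3 libraries. The common biological coefficient of variation was 0.106. Counts limit the precision of low genes, and floors from a count of 0 cover counting error only.

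Gene lists for brain cell types, hormone and transmitter systems, cell processes and tissues that could be carried along were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. The 25 lists with at least 3 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), beside camera with an estimated correlation and fry, adjusted over the lists of a comparison. Named genes have a symbol, pass the threshold, have a mean of at least 1 CPM in a group and show no overlap between the replicates of both groups. The 12 largest rises and falls were taken for each mutant in each sex and for wild-type sex, and 5 and 5 elsewhere, with up to 4 members of each list and up to 2 rises and 2 falls without a symbol. Genes outside this rule are marked as chosen after their values were seen.

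Shared calls of both mutants were set beside the number 2 independent sets would share and beside 20 simulated sets of unchanged groups. In these sets all 18 libraries, wild type included, were redrawn from 1 mean per gene, and both mutants were tested against the same redrawn wild type. Positions on chromosomes were tested with two-sided Fisher's exact tests. Shares of counts on gene classes were compared by exact permutation, where the smallest two-sided p of 3 against 3 is 0.1. The procedure was tested on simulated data with the depths and spreads of these libraries. In the comparison of oxt mutant and wild-type females, 58.2% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, with 7 false calls among 158. For the difference of an effect between the sexes, 53.7% of genes changed 2-fold were recovered.

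Replicate numbers 1 to 3 recur in every group. The same-numbered libraries of both groups moved together in every pair, with correlations above 0.1, only for males against females in oxtr1 mutants, so values with replicate number as a block stand beside that comparison. The libraries numbered 3 separated from the others in all 6 groups, so counts from the libraries numbered 1 and 2 alone stand beside the pooled ones. A batch of number 3 alone holds 1 library per group and gives no value of its own. Alternatives were DESeq2 1.42.0, other size factors, other filters, a fit of the compared groups alone, a robust fit, a replicate block, a pituitary score as covariate, library sizes without pituitary hormones, and leaving out each library. Fits of the libraries numbered 1 and 2 alone, with a term for number 3, on genes without shared exon bases and without the 10 most counted genes in the library size were added after the data were seen. No genome sequence was at hand, so base composition was not examined.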

Results

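Brain transcripts of adult medaka were compared between wild-type fish, fish homozygous for the I22F change in oxt, the gene of the neuropeptide oxytocin (isotocin in fish), and fish labelled oxtr1-/-, mutant in an oxytocin receptor gene. The series asks how the expression profiles of these genotypes differ in both sexes. Each of the 6 groups of genotype and sex had 3 libraries of 2 brains each. The total count per library ran from 10232550 in wild-type female replicate 3 to 15755936 in oxt female replicate 1. Between 21156 and 21552 genes had a count in a library, and 18723 were tested. Across genes, which are not independent replicates, log2 CPM of libraries of a group correlated with r between 0.978 and 0.989. The 10 most counted genes took between 23.9% and 34.8% of the counts of a library, led by herc4 and a short gene inside it on chromosome 15, which share the same reads and took 9.49% each. ENSORLG00000009674, ENSORLG00000022220 and ENSORLG00000021050 (1.76% each) also overlap each other, so the summed share counts some reads more than once. Genes of the mitochondrial chromosome took between 3.56% and 6.28%.

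The first principal component held 26.9% of the variance and set the oxtr1 mutants apart from the other genotypes. The second held 17.5% and parted oxt mutants from wild type. The third held 10.3% and set the libraries numbered 3 apart from those numbered 1 and 2 in all 6 groups. Across genotypes sex did not separate the libraries on these components, though oxt males lay above oxt females on the first and second. On the fourth (5.45% of variance) each female library lay above the same-numbered male library of its genotype.

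**Figure D1:**
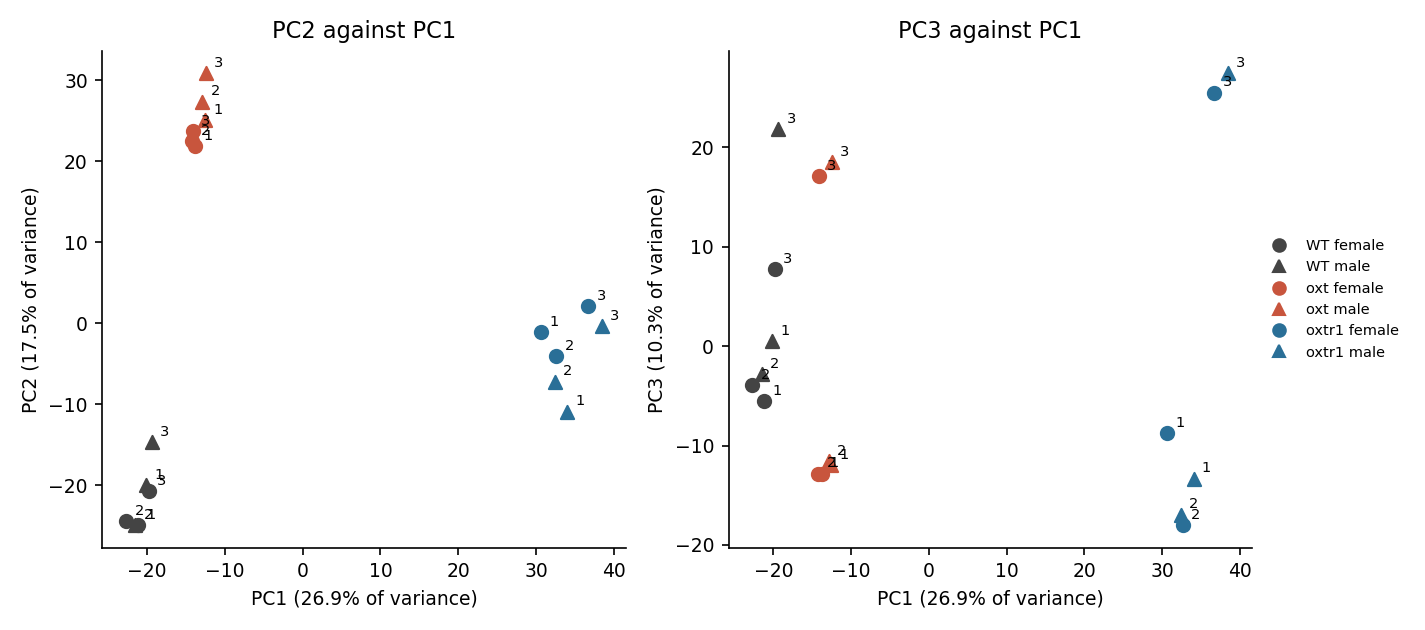
Principal components of log2 CPM, each point a library, with colour for genotype, shape for sex and the replicate number beside it. The first component (26.9% of variance) separates oxtr1 mutants, the second (17.5%) parts oxt mutants from wild type, and the third (10.3%) is higher for number 3 than for numbers 1 and 2 within each group.

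The mutated genes themselves were measured first. The oxytocin transcript (LOC101160739, ENSORLG00000003809, chromosome 9 from 7693520 to 7695448 of the ASM223467v1 assembly) was higher in oxt mutants than in wild type. Its level was 15.4 ± 3.34 CPM in wild-type and 39.5 ± 4.24 CPM in oxt mutant females, 2.59-fold higher (log2 fold change 1.37, SE 0.22, adjusted p = 0.001). In males it was 12.1 ± 3.19 CPM in wild type and 25.7 ± 2.58 CPM in oxt mutants, 2.14-fold higher (SE of the log2 fold change 0.23, adjusted p = 0.00713). The male call was lost without wild-type male replicate 2 (adjusted p = 0.06). In oxtr1 mutants the level was 15.9 ± 3.22 CPM in females and 15.8 ± 5.89 CPM in males, with adjusted p of 0.912 and 0.408 against wild type. Of its 752 exon bases, 547 (72.7%) are shared with LOC101161247 on the opposite strand. That gene has 5872 exon bases and had 38.4 ± 3.94 CPM in oxt mutant females and 25.1 ± 2.72 CPM in oxt mutant males, less than oxytocin. The bases it does not share thus held fewer reads than those oxytocin does not share.

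Vasotocin, the related peptide gene on chromosome 9 from 7732229 to 7735835 that RefSeq calls oxt (ENSORLG00000022162), had 4.45 ± 1.15 CPM in wild-type and 8.39 ± 1.95 CPM in oxt mutant females (log2 0.94, adjusted p = 0.0953; 0.0483 with replicate number as a block and 0.0226 when only its groups were fitted). In males it had 5.73 ± 1.15 and 10.4 ± 3.03 CPM (log2 0.87, adjusted p = 0.111; 0.0578 and 0.0474 in these fits). Averaged over the sexes its rise in oxt mutants passed the test (log2 0.91, SE 0.23, adjusted p = 0.009). The mutated receptor gene itr1 (ENSORLG00000003297, chromosome 5 from 7010761 to 7017321) had between 0 and 4 counts per library and was not tested, so no change of its transcript was detectable at this depth. The other oxytocin receptor, oxtr on chromosome 5, had 4.23 ± 0.408 CPM in wild-type females and 5.04 ± 0.532 CPM in oxtr1 mutant females (adjusted p = 0.515). Neither oxtr nor the vasotocin receptor avpr2 on chromosome 7 passed the test in any of the 12 comparisons. As a list, the 4 tested genes of the oxytocin and vasotocin system passed camera in oxt males (adjusted p = 0.0429; 0.28 with an estimated correlation as adjusted p) and not in oxt females (0.179) or in oxtr1 females and males (0.606 and 0.439). The call in oxt males was lost in the libraries numbered 1 and 2 alone (0.123) and with replicate number as a block (0.0659), and the difference between the sexes did not pass (0.737).

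**Figure D2:**
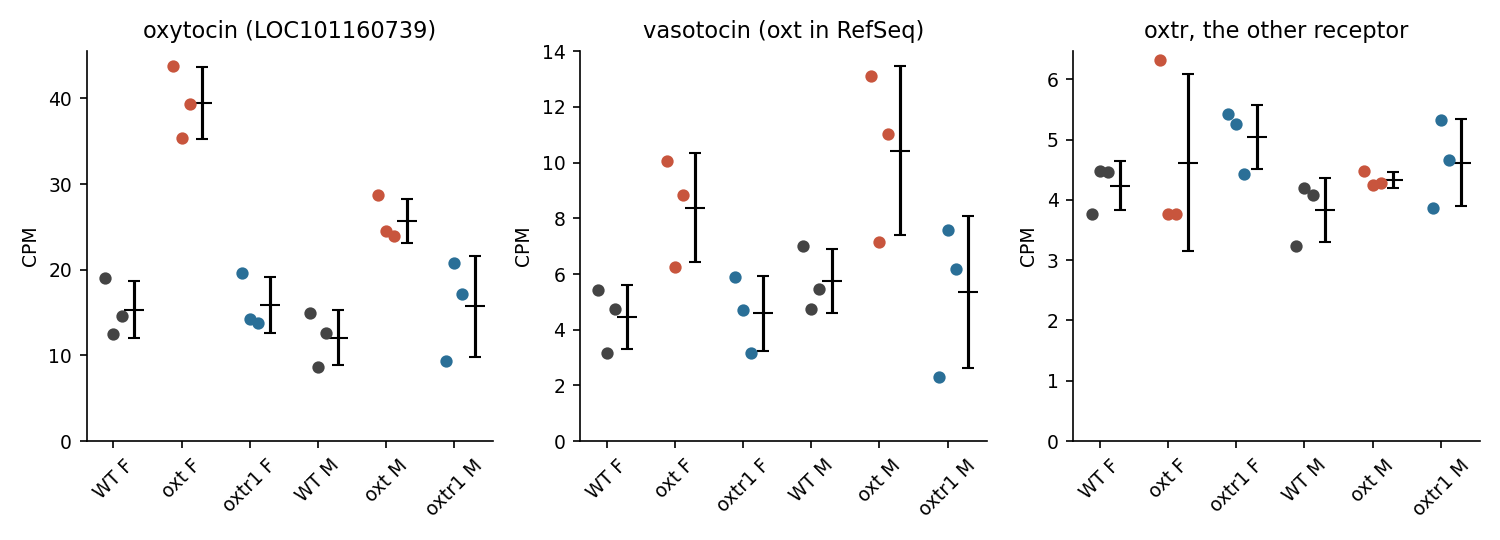
Levels (CPM) of oxytocin, vasotocin and the receptor oxtr per library (dots), with group mean and SD (bars, n = 3 libraries) for each genotype in females (F) and males (M). Oxytocin reaches 39.5 CPM in oxt mutant females and 25.7 CPM in oxt mutant males, against 15.4 and 12.1 CPM in wild type.

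Brains of oxt mutants asked what changes when oxytocin itself is altered. With the preset correlation, the lists of hypothalamic neuropeptides and of blood vessel cells were higher than in wild type and that of microglia was lower in both sexes. With an estimated correlation each of the 3 passed in 1 sex only, and a minority of their genes was called. Of 25 tested hypothalamic neuropeptides, 5 rose and 0 fell in females (9 rose and 1 fell adjusted over the list alone), and 7 rose and 0 fell in males (12 and 0 adjusted over the list alone). Among them, cck (cholecystokinin) rose by 0.86 on the log2 scale in females and 0.59 in males, and penk (proenkephalin) by 0.74 and 0.91. Neuropeptide B, npb (the gene on chromosome 8, ENSORLG00000025130, here and below), went from 7.43 ± 2.32 to 24.7 ± 2.08 CPM in females (3.36-fold, adjusted p = 7.71e-05). In males it had 2.33 ± 0.317 and 3.06 ± 0.695 CPM, and the difference of its effect between the sexes did not pass (log2 -1.37, adjusted p = 1). A part of npb, 682 exon bases, is shared with LOC101174025, so its reads may belong to either gene. The neuropeptide list passed camera in females (adjusted p = 5.04e-06; adjusted p = 0.0513 with an estimated correlation) and in males (4.78e-07; adjusted p = 0.0401 with an estimated correlation).

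Of 23 genes of vessels and meninges, 9 rose and 0 fell in oxt females (11 and 0 adjusted over the list alone), and 7 rose and 0 fell in males (10 and 0). The endothelial receptor kdr rose by 0.85 in females and 0.77 in males on the log2 scale, the efflux pump abcb1 by 0.83 and 0.82, and the receptor flt1 by 0.84 and 0.75. The list passed in females (adjusted p = 7.57e-06; 0.0428 as adjusted p with an estimated correlation) and in males (0.000428; adjusted p = 0.062 with an estimated correlation). Of 8 microglia and macrophage genes, 2 fell and 0 rose in each sex (4 adjusted over the list alone). The lysosomal enzyme hexb fell by 0.60 and 0.55 on the log2 scale in females and males, and irf8, a macrophage transcription factor, fell by 0.94 in females, with log2 -0.49 and adjusted p = 0.0546 in males (adjusted p = 1 for the difference between the sexes). The list passed in both sexes (adjusted p = 0.00482 and 0.00102; adjusted p = 0.0513 and 0.0401 with an estimated correlation).

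Other lists moved in oxt mutants with the preset correlation, but none of these passed with an estimated one. General neuron genes were higher (5 of 17 in females and 4 in males, 0 lower; adjusted p = 2.15e-05 and 7.2e-05; adjusted p = 0.303 and 0.28 with an estimated correlation), among them the synaptic gene snap25 (log2 0.55 and 0.47). Of 43 nuclear genes of oxidative phosphorylation, 9 and 3 were higher and 0 lower (1.67e-08 and 1.43e-06; adjusted p = 0.12 and 0.242 with an estimated correlation), led by sdhaf4, a succinate dehydrogenase assembly factor (log2 0.90 and 0.79). Of 57 ribosomal protein genes, 5 and 14 were higher and 0 lower (6.25e-08 and 3.48e-13; adjusted p = 0.303 and 0.242 with an estimated correlation). Of 27 cell division and neurogenesis genes, 2 were lower in females, sox11 and bub1, and 1 in males, neurod1 (0.00134 and 1.39e-05; adjusted p = 0.417 and 0.314 with an estimated correlation). In the libraries numbered 1 and 2 alone the cell division call was lost in females (0.353) and passed in males (0.045). Of 12 pituitary transcription factors and receptors, the prohormone convertases pcsk1 and pcsk2 rose in both sexes (0.0056 and 0.00288; adjusted p = 0.303 and 0.255 with an estimated correlation). Among 19 stress genes, the collagen chaperone serpinh1, hsc70 and xbp1 rose in both sexes (0.00768 and 0.0337; adjusted p = 0.303 and 0.28 with an estimated correlation), and the list call in males was lost in the libraries numbered 1 and 2 alone (0.071).

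Among the largest single changes in oxt mutants was sts (steroid sulfatase), which rose from 0.902 ± 0.42 to 6.38 ± 1.67 CPM in females (7.24-fold, adjusted p = 0.000742) and from 0.652 ± 0.446 to 7.76 ± 1.87 CPM in males (11.6-fold, adjusted p = 0.000106). The chromatin remodeller smarcad1 rose from 45.4 ± 7.44 to 318 ± 105 CPM in females and from 40.9 ± 3.34 to 248 ± 45 CPM in males, though 471 of its exon bases are shared with ENSORLG00000004857. The deiodinase dio1, which acts on thyroid hormone, rose 5.20-fold and 4.98-fold. The muscle oxygen carrier myoglobin, mb, rose from 4.71 ± 1 to 15 ± 2.88 CPM in females. Among the falls, the spindle gene aspm went from 42.9 ± 5.42 to 13.9 ± 1.69 CPM in females, parp4 from 26.7 ± 2.36 to 10.5 ± 0.386 CPM in females, and the homeobox gene nkx2-5 fell by 1.80 and 2.53 on the log2 scale. The ubiquitin ligase gene rnf180 fell by 1.39 and 1.47, and that call was lost in the libraries numbered 1 and 2 alone in both sexes. In males gnrh2, a gonadotropin-releasing hormone gene, had 0.358 ± 0.314 and 1.44 ± 0.591 CPM, and its call was lost without any of 4 libraries (wild-type male replicates 2 and 3, oxt male replicates 1 and 2; highest adjusted p 0.155). The female calls of gjd4, bche and npff each rested on 1 wild-type library, replicate 1 for gjd4 (adjusted p = 0.0537 without it) and npff (0.0785) and replicate 2 for bche (0.109). Genes without a symbol gave some of the largest differences: ENSORLG00000025272 on chromosome 21 had 5.5 ± 0.873 CPM in wild-type and 0.0438 ± 0.0759 CPM in oxt mutant females, with 306 exon bases shared with ENSORLG00000023393.

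In all, 1275 genes were called in oxt females (735 higher, 540 lower) and 1133 in oxt males (613 higher, 520 lower), 233 and 241 of them changed at least 2-fold. With the libraries numbered 1 and 2 alone the counts were 1229 and 1226. The female count fell to 650 without wild-type replicate 1, 709 without wild-type replicate 2, 693 without oxt replicate 1 and 718 without oxt replicate 2, and the male count to 743, 471, 693 and 609 without the same replicates of males. Between the sexes 653 calls were shared, all in the same direction, against 39.1 for independent sets, and 700 in the libraries numbered 1 and 2 alone.

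Brains of oxtr1 mutants asked what changes when a receptor for oxytocin is mutated. Microglia transcripts were lower in both sexes, the noradrenaline transporter transcript was higher, and a set of single genes changed several-fold. Of 8 microglia and macrophage genes, 5 fell and 0 rose in each sex (6 in females and 5 in males adjusted over the list alone). In females and males hexb fell by 0.78 and 0.65 on the log2 scale, irf8 by 0.88 and 0.78, and the leukocyte phosphatase gene ptprc by 0.67 and 0.71. The list passed camera in females (adjusted p = 2.99e-06; 0.00437 as adjusted p with an estimated correlation) and in males (0.000133; 0.0126 as adjusted p with an estimated correlation).

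The noradrenaline transporter slc6a2 rose by 0.79 and 1.06 on the log2 scale in females and males, and phox2a, a transcription factor of noradrenergic neurons, from 8.87 ± 0.761 to 41.3 ± 20.6 CPM and from 8.85 ± 0.786 to 53.9 ± 29.6 CPM. Since 4491 exon bases are shared by phox2a and inppl1, which rose 5.06-fold and 7.39-fold, the reads of this pair cannot be assigned. The list of 22 monoamine genes as a whole did not pass (adjusted p = 0.976 and 0.718). Brain aromatase, cyp19b, which makes oestrogen in radial glia, fell from 155 ± 6.96 to 115 ± 23.8 CPM in females and from 76.8 ± 3.92 to 55.7 ± 7.74 CPM in males (adjusted p = 0.024 and 0.0263). Both aromatase calls were lost in the libraries numbered 1 and 2 alone and without any of 5 of the 6 libraries compared (highest adjusted p 0.119 and 0.115). The glial gene s100b rose by 1.03 and 0.95, and serpinh1 and the heat shock gene dnajb1 rose in both sexes. Of 12 circadian genes, clock fell by 0.82 and 0.53 on the log2 scale and dec1a by 0.43 and 0.57. In contrast hlf rose by 0.38 in females (adjusted p = 0.00907; log2 0.25 and adjusted p = 0.109 in males). The circadian list did not pass (adjusted p = 0.976 and 0.364). In the ribosomal list, rpl28 fell by 0.50 in each sex, while the list did not pass (adjusted p = 0.115 and 0.536; higher in females in the libraries numbered 1 and 2 alone, 0.00244), nor did vessels and meninges (0.207 and 0.726).

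In females more lists passed with the preset correlation than in males. Neuron genes (adjusted p = 0.000344 in females and 0.621 in males; females adjusted p = 0.497 with an estimated correlation) and nuclear genes of oxidative phosphorylation (8.76e-08 and 0.0598; females adjusted p = 0.297 with an estimated correlation) were higher, with snap25 up by 0.84 and 0.52 and sdhaf4 by 1.11 and 0.97 on the log2 scale. Neuropeptides passed in females (0.0178; adjusted p = 0.472 with an estimated correlation), where 2 of 25 rose, penk and cck, and not in males (0.171), where penk rose by 0.86. Stress genes passed in females (0.0153; adjusted p = 0.472 with an estimated correlation) and not in males (0.231), as did pituitary transcription factors and receptors (0.0353 and 0.621; females adjusted p = 0.497 with an estimated correlation), of which pitx1 rose in both sexes. The difference of the effect between the sexes passed for neurons and oxidative phosphorylation only with the preset correlation (0.000449 and 0.000272; adjusted p = 0.625 for both with an estimated one). It did not pass for neuropeptides (0.448), stress genes (0.322) or pituitary transcription factors and receptors (0.21), so these lists are not shown to differ between the sexes. Cell division genes were lower (0.0236 and 0.00505; adjusted p = 0.797 and 0.922 with an estimated correlation), with mcm2 called in both sexes, and both list calls were lost in the libraries numbered 1 and 2 alone (0.101 and 0.0852).

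The largest fall of a gene with a symbol in oxtr1 mutants was that of the ubiquitin ligase gene rlim, from 805 ± 142 to 49.8 ± 6.13 CPM in females and from 584 ± 72.8 to 46.6 ± 0.932 CPM in males, with 417 exon bases shared with ENSORLG00000006138. The homeobox gene pitx1 rose from 1.7 ± 0.679 to 8.75 ± 0.858 CPM in females and from 1.84 ± 0.491 to 8.27 ± 2.64 CPM in males. The kinase gene matk rose 4.63-fold and 4.69-fold, the myosin gene myo7a 7.69-fold and 7.55-fold, and tmem244 11.8-fold and 9.44-fold. Rises of dus4l (4.54-fold and 6.19-fold) and acbd4 (4.55-fold and 5.95-fold) were found in both sexes. The gene sts rose 6.72-fold and 11.3-fold, as it had in oxt mutants. Among the falls, tat (tyrosine aminotransferase, with 947 shared exon bases) fell by 2.38 and 2.62 on the log2 scale, the autophagy gene map1lc3c by 2.46 and 2.24, bmper, a regulator of bone morphogenetic proteins, by 1.62 and 2.52, and aspm by 1.82 and 1.25. ENSORLG00000028839 on chromosome 6 had 0 counts in wild type and 4.7 ± 2.64 CPM in oxtr1 females and 5.78 ± 0.419 CPM in oxtr1 males.

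In all, 1627 genes were called in oxtr1 females (850 higher, 777 lower) and 1103 in oxtr1 males (571 higher, 532 lower), 435 and 395 of them changed at least 2-fold. With the libraries numbered 1 and 2 alone the counts were 1273 and 853, and the male count was 687 when only its own groups were fitted. The female count fell to 986 without wild-type replicate 1 and 1023 without wild-type replicate 2, and the male count to 701 without wild-type replicate 2. Between the sexes 671 calls were shared, all in the same direction, against 48 for independent sets, and 495 in the libraries numbered 1 and 2 alone.

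**Figure D3:**
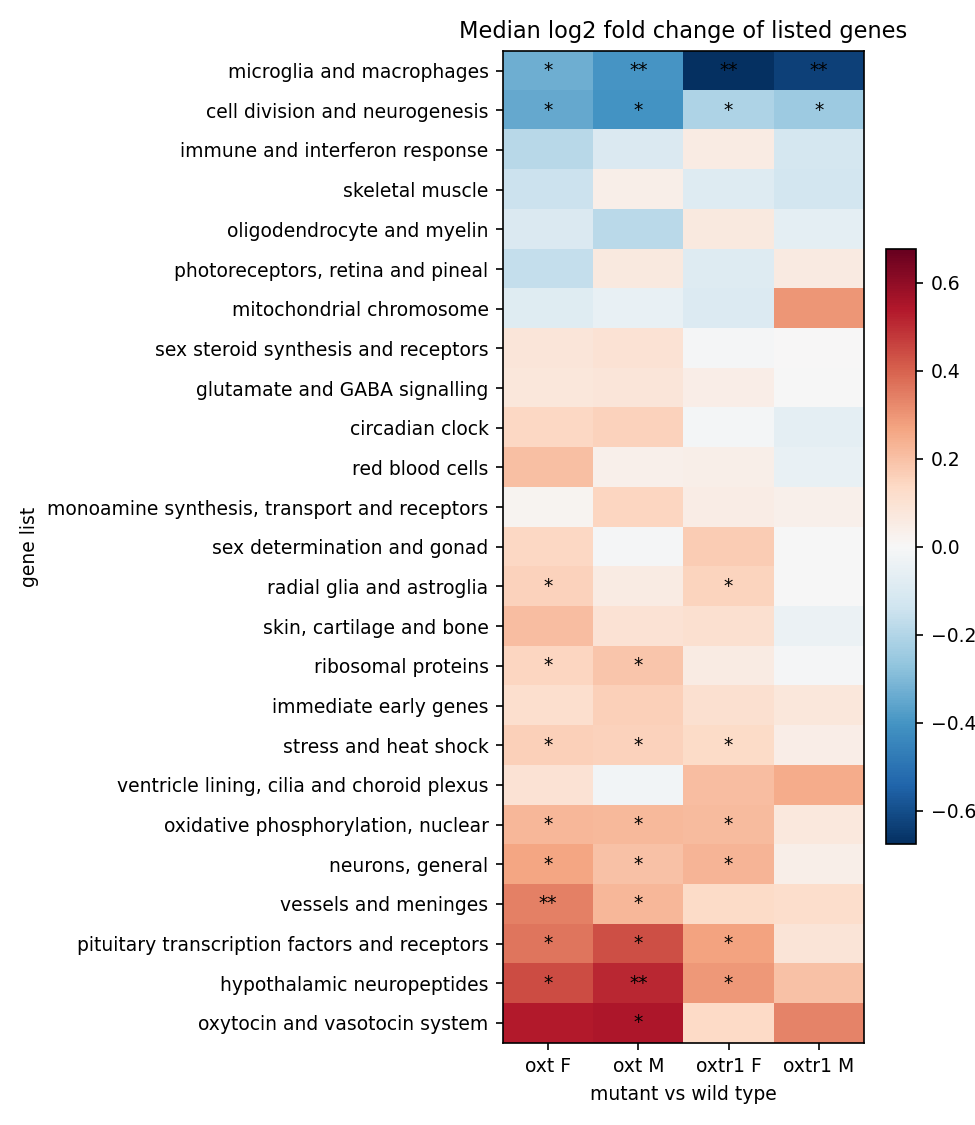
Median log2 fold change of the tested members of 25 gene lists (lists on the vertical axis) for each mutant against wild type in females (F) and males (M). One star marks an adjusted camera p under 0.05 with the preset correlation alone, and a pair of stars one that also holds with an estimated correlation, as for microglia in oxtr1 mutants (0.00437 and 0.0126).

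The remaining lists gave smaller or mixed changes. Of 31 genes of glutamate and GABA signalling, 5 rose and 3 fell in oxt females and 3 rose and 3 fell in oxt males, with camera adjusted p between 0.124 and 0.769 over the 4 comparisons of a mutant with wild type in a sex. Circadian genes had adjusted p between 0.052 and 0.976, with hlf higher in oxt mutants by 0.45 in females and 0.61 in males. Their list passed as higher in the libraries numbered 1 and 2 alone in oxt females and males (0.0147 and 0.0102) and with replicate number as a block in oxt males (0.0281). Radial glia genes passed in oxt females (0.0224; adjusted p = 0.303 with an estimated correlation) and oxtr1 females (0.0353; adjusted p = 0.497 with an estimated correlation) and not in males (0.321 and 0.773), but the difference between the sexes did not pass for either mutant (0.367 and 0.072). The lowest adjusted p of the 4 was 0.053 for immediate early genes, 0.052 for monoamine genes, 0.124 for immune and interferon genes, 0.123 for oligodendrocytes and myelin, and 0.64 for the ventricle lining. It was 0.121 for photoreceptors and pineal, 0.54 for red blood cells, 0.354 for skeletal muscle, 0.115 for skin, cartilage and bone, 0.264 for sex determination and gonad genes, 0.666 for sex steroid genes and 0.0598 for the mitochondrial chromosome. Some of these calls depend on the libraries and the fit. In all 18 libraries without the block, no list in this paragraph passed with an estimated correlation in the 4 comparisons. In the libraries numbered 1 and 2 alone immediate early genes passed as higher in oxt females and males (0.0246 and 0.0249) and monoamine genes in oxt males (0.0334). Mitochondrial genes passed there as lower in oxt and oxtr1 females (0.0011 and 0.00249). With the block they passed as higher in oxtr1 males (0.00268). Median, mean and test of a list differed in sign only in lists that did not pass, such as skeletal muscle in oxt females (median -0.14, mean 0.12). The lists of pituitary hormones, lens, and liver and egg proteins had too few tested members for a test. The matched pituitary hormones together took 11.8 ± 2.12 CPM in wild-type females and 27.3 ± 7.57 in oxt females, and 4.49 ± 0.419 and 7.36 ± 1.96 in males (exact permutation p = 0.1 each, the smallest that 3 against 3 allows; adjusted p = 0.467). In oxtr1 females and males they took 18.6 ± 9.5 and 9.08 ± 4.09 CPM (exact p = 0.4 and 0.3).

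Males and females of each genotype were compared to find sex differences that the mutations might alter. Few genes differed, and 3 of them differed in every genotype. Galanin, gal, a neuropeptide gene, was higher in males, with 2.91 ± 1.12 and 11.4 ± 1.83 CPM in wild-type females and males, 3.12 ± 0.926 and 16.2 ± 2.57 CPM in oxt mutants and 2.84 ± 0.308 and 11.5 ± 5.96 CPM in oxtr1 mutants. Brain aromatase, cyp19b, was higher in females, by 2.01-fold in wild type, 2.03-fold in oxt mutants and 2.06-fold in oxtr1 mutants. Neuropeptide B, npb, was higher in females as well, with 7.43 ± 2.32 and 2.33 ± 0.317 CPM in wild type, 24.7 ± 2.08 and 3.06 ± 0.695 CPM in oxt mutants and 11.8 ± 4.19 and 2.16 ± 0.226 CPM in oxtr1 mutants. The list of 15 sex steroid genes was lower in wild-type males (adjusted p = 0.0163; adjusted p = 0.304 with an estimated correlation) and oxt males (0.00726; adjusted p = 0.165 with an estimated correlation), with 0.191 in oxtr1 males. The call in oxt mutants was lost in the libraries numbered 1 and 2 alone (0.184), and the sex difference of this list in oxt and oxtr1 mutants did not differ from that in wild type at the threshold (0.984 and 0.558).

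**Figure D4:**
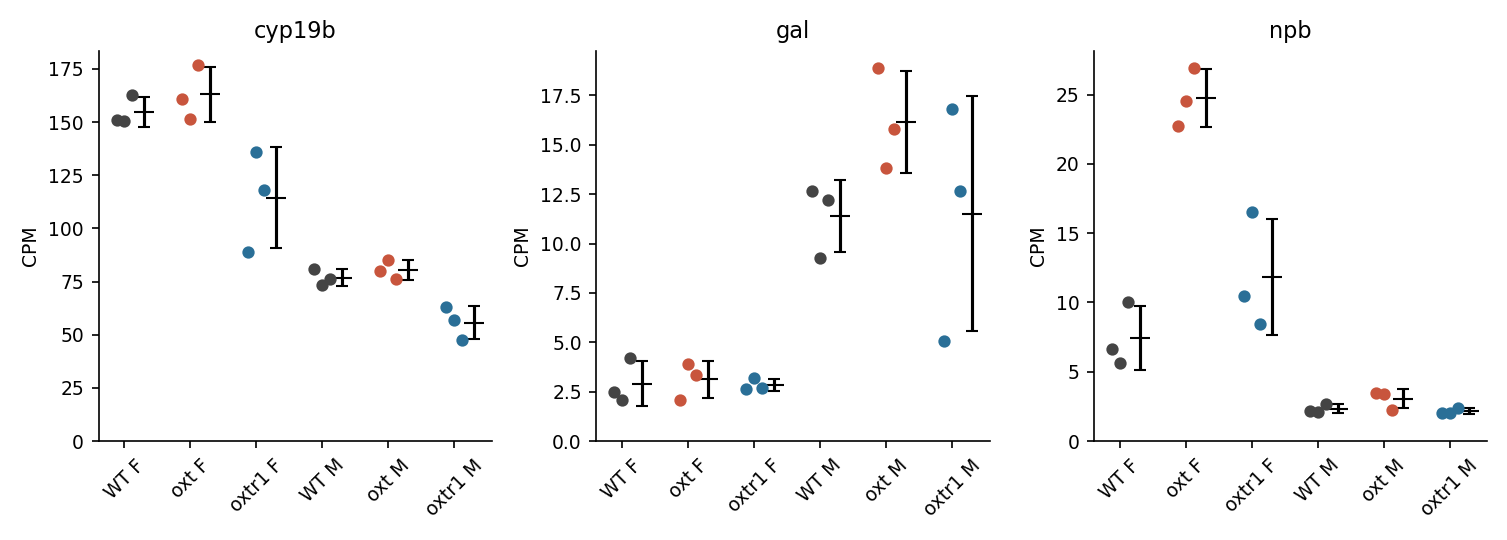
Levels (CPM) of cyp19b, gal and npb per library (dots), with group mean and SD (bars, n = 3 libraries), for the 3 genotypes in females (F) and males (M). Brain aromatase is 155 CPM in wild-type females and 76.8 CPM in males, and npb reaches 24.7 CPM in oxt mutant females.

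In wild type 6 genes were called by edgeR, 2 higher and 4 lower in males (18 with DESeq2, 5 in the libraries numbered 1 and 2 alone). The clotting factor gene f13a1 had 96.7 ± 14.2 CPM in females and 1.83 ± 0.383 CPM in males, uso1 on chromosome 1 had 25.2 ± 2.15 and 49.7 ± 4.52 CPM, with 477 exon bases shared with coro2a, and LOC100125524 had 21.9 ± 2.47 and 12.3 ± 1.83 CPM. The wild-type calls of gal, npb and LOC100125524 were lost without any of 5 or more libraries (highest adjusted p 0.297 for gal), and the count fell to 3 without wild-type female replicate 1 or 3 or wild-type male replicate 2 or 3. Nuclear genes of oxidative phosphorylation were higher as a list in wild-type males (8.54e-06; adjusted p = 0.377 with an estimated correlation), with 0 of 43 genes called. Neuron genes (0.0129; adjusted p = 0.849 with an estimated correlation) and oligodendrocyte genes (0.0284; adjusted p = 0.734 with an estimated correlation) also passed, the latter not in the libraries numbered 1 and 2 alone (0.23).

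In oxt mutants 11 genes were called, 3 higher and 8 lower in males (23 with DESeq2, 9 in the libraries numbered 1 and 2 alone, 6 among genes without shared exon bases). They were gal, npb, cyp19b, uso1, f13a1 (66.4 ± 14.8 CPM in females and 5.38 ± 2.39 CPM in males), hebp3, LOC101171549, LOC101166176, LOC101174025, LOC105354644 and ENSORLG00000027443. The count fell to 7 without oxt female replicate 3, oxt male replicate 1 or oxt male replicate 3, and 5 of the 6 wild-type calls were among the 11. In the libraries numbered 1 and 2 alone wild type and oxt mutants shared 3 calls. In oxtr1 mutants 4 genes were called, gal (higher in males), cyp19b, npb and LOC101174025 (lower), and 1 was called among genes without shared exon bases. The calls of npb and LOC101174025, here and in oxt mutants, may rest on the same reads. With replicate number as a block 11 were called, 2 higher and 9 lower (13 with DESeq2, 9 in the libraries numbered 1 and 2 alone, 0 when only these 6 libraries were fitted). The oxtr1 call of gal was lost in the libraries numbered 1 and 2 alone and without any of 5 libraries (highest adjusted p 0.226). The count was 7 without oxtr1 female replicate 2, 8 without female replicate 3 and 10 without male replicate 2. As lists in oxtr1 males, mitochondrial genes were higher (0.000135, blocked 2.44e-08; adjusted p = 0.761 with an estimated correlation), and ribosomal (6.53e-07, blocked 1.09e-07; adjusted p = 0.761 with an estimated correlation), immune (0.043, blocked 0.038; adjusted p = 0.58 with an estimated correlation) and neuron genes (0.043; adjusted p = 0.761 with an estimated correlation) were lower, and the neuron call was lost with the block (0.0659). In oxt males, oxidative phosphorylation, neuron and ribosomal genes were higher as lists (0.00617, 0.0434 and 0.0367; adjusted p = 0.782 for each with an estimated correlation), and the neuron and ribosomal calls were lost in the libraries numbered 1 and 2 alone (0.175 and 0.49).

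Whether a mutation acted differently in males and females was tested gene by gene. No gene passed in edgeR for oxt (0 called, 432 at an unadjusted p under 0.05, 1 with DESeq2, 1 in the libraries numbered 1 and 2 alone). For oxtr1 0 were called by edgeR as well, with 1248 at an unadjusted p under 0.05 and 1 called with DESeq2 or in the libraries numbered 1 and 2 alone. The oxtr1 count was 2 without oxtr1 female replicate 2 and 4 without oxtr1 male replicate 2. If no gene differed, a share of 0.05 of the 18723 tested genes would have an unadjusted p under 0.05. The 432 for oxt lie under that share and the 1248 for oxtr1 over it, but genes are not independent. The smallest unadjusted p for oxtr1 among genes with a symbol was that of prph, a neuronal filament gene (log2 -1.16, unadjusted p = 1.95e-05, adjusted p = 0.365). For oxt it was that of mthfd2 (log2 -0.92, unadjusted p = 0.000178, adjusted p = 1).

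Both mutants were then set side by side, since a change in the oxytocin gene and one in a receptor gene could alter the same genes. In females 513 genes were called in both mutants in the same direction (279 higher, 234 lower) and 17 in opposite directions, against 55.8 shared by independent sets. In males 231 were shared (84 higher, 147 lower) and 18 were opposite, against 33.5. At an unadjusted p under 0.01, 827 genes in females and 404 in males were shared in the same direction. Simulated unchanged groups, with the wild type redrawn as well, shared a mean of 22.5 and 23.1 over 20 runs (highest 37 and 31). The simulation holds only random spread of the shared controls. It cannot show how many shared calls come from a difference of the wild-type fish from both lines. At the adjusted threshold the counts were 428 and 196 in the libraries numbered 1 and 2 alone. Across genes, which are not independent replicates, the fold changes of both mutants correlated with r = 0.521 in females and 0.465 in males, while sharing redrawn wild-type libraries gave 0.507 and 0.488 in the simulations. The covariance was 0.132 and 0.125, against 0.028 and 0.0271 in the simulations. In both sexes of both mutants 140 genes were called in the same direction (54 higher, 86 lower), with sts among the higher and hexb among the lower.

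Tested directly against each other, with the sexes averaged, 3181 genes differed between oxtr1 and oxt mutants (1531 higher and 1650 lower in oxtr1; 2961 in the libraries numbered 1 and 2 alone). Against wild type the averaged counts were 3541 for oxt (1897 higher, 1644 lower; 3323 in the libraries numbered 1 and 2 alone) and 2862 for oxtr1 (1469 higher, 1393 lower; 2375). Oxytocin was lower in oxtr1 than in oxt mutants (2-fold, SE of the log2 fold change 0.16, adjusted p = 0.000169), as was vasotocin (log2 -0.90, adjusted p = 0.00897). The genes gjd4 and bche were 12.1-fold and 11.1-fold higher in oxtr1 mutants, and rlim, smarcad1 and tyrp1, a pigment gene, were 6.09-fold, 5.57-fold and 4.18-fold lower. Vessel genes (2 higher, 8 lower of 23), neuropeptides (0 and 6 of 25), circadian genes (0 and 6 of 12) and ribosomal protein genes (1 and 23 of 57) were lower in oxtr1 than in oxt mutants (adjusted p = 0.00439, 0.00607, 0.00439 and 6.77e-10; adjusted p = 0.31, 0.329, 0.329 and 0.408 with an estimated correlation). Averaged over the sexes, the neuropeptide, microglia and vessel lists of oxt mutants and the microglia list of oxtr1 mutants passed with an estimated correlation (adjusted p = 0.0261 for each of the 3 and 0.00334).

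Called genes were not spread evenly over the chromosomes. The exact tests take genes as independent, but called genes lay side by side 1.52 to 2.12 times as often as permuted. The p-values of this part can therefore be too small. In oxt mutants chromosomes 5 (odds ratio 1.49 in females and 1.69 in males) and 13 (1.44 in each sex) held more calls than the rest of the genome, and chromosomes 19 (0.436 and 0.474) and 3 (0.561 and 0.554) held fewer. In 1 sex of oxt mutants, chromosome 12 in females (1.44) and chromosomes 2 (1.60) and 4 (1.41) in males held more and chromosome 11 in males fewer (0.412). At an unadjusted p under 0.01 the calls of chromosomes 13 (adjusted p = 0.13 and 0.168), 12 (0.127) and 2 (0.385) were lost. With the sexes averaged only 5, 19 and 3 of these chromosomes passed. In oxtr1 mutants chromosome 12 held more (1.84 and 2.06) and chromosome 11 fewer (0.353 and 0.331) in both sexes, and in males alone chromosomes 4 (1.86) and 6 (1.64) held more and 23 (0.243), 8 (0.45) and 7 (0.632) fewer. Chromosomes 4, 23 and 7 passed in females too at an unadjusted p under 0.01 (adjusted p = 0.00806, 0.0128 and 0.00932). Averaged over the sexes, 5 chromosomes held more calls in oxtr1 mutants and 4 held fewer. Chromosome 5, which carries itr1, was among those with more (odds ratio 1.26, adjusted p = 0.0302). Differences between the sexes in these shares were not tested. Near the mutated genes, 30 of 291 genes within 5 Mb of oxytocin (10.3%) were called in oxt females against 6.75% elsewhere (odds ratio 1.59, Fisher's exact p = 0.0248), and 28 (9.62%) in oxt males against 6% (1.67, exact p = 0.0175). Among genes at an unadjusted p under 0.01 the odds ratios were 1.47 (exact p = 0.0268) and 1.31 (exact p = 0.139). With a window of 2 Mb the odds ratios were 2.47 (exact p = 0.000361) and 2.36 (exact p = 0.00132), and with 10 Mb they were 1.34 (exact p = 0.0596) and 1.28 (exact p = 0.125). All these windows include oxytocin itself and the overlapping LOC101161247, both called in each sex, so the shares rest in part on the mutated gene. Around itr1 on chromosome 5, 27 of 280 genes were called in oxtr1 females (odds ratio 1.12, exact p = 0.523) and 13 in oxtr1 males (0.775, exact p = 0.443). Within 2 Mb of itr1 the odds ratios were 1.52 (exact p = 0.159) and 0.478 (exact p = 0.29). Chromosome 1 carries the sex-determining region of medaka. Of its 979 tested genes, 1 was called for sex in wild type (odds ratio 3.63, exact p = 0.276), 2 in oxt mutants (4.03, exact p = 0.11) and 0 in oxtr1 mutants. Only among genes that differed between the sexes at an unadjusted p under 0.01 was chromosome 1 over-represented, in wild type (odds ratio 2.72, exact p = 9.24e-07) and oxt mutants (2.43, exact p = 0.000731). Its odds ratio there was 0.776 in oxtr1 mutants (exact p = 0.56). The difference between genotypes was not tested.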

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

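The tests of effects that differ between the sexes were planned, over 25 lists in each mutant. Shown here are only the lists that passed, 1 for oxt and 4 for oxtr1, so they were picked by their result. Each result below is a gene list whose mutant effect differed between males and females with the preset correlation, and for none of them did the difference hold with an estimated one.

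In oxt mutants, photoreceptor, retina and pineal genes had a median log2 change against wild type of -0.16 in females and 0.07 in males (adjusted p = 0.0262 for the difference, 9 of 13 genes higher in the male effect; adjusted p = 0.116 with an estimated correlation), and this call was also lost with the replicate block (0.0514) and in the libraries numbered 1 and 2 alone (0.14). In oxtr1 mutants, genes of the mitochondrial chromosome had a median of -0.10 in females and 0.30 in males (adjusted p = 5.47e-05, 37 of 37 genes higher in the male effect; adjusted p = 0.625 with an estimated correlation). General neuron genes had medians of 0.23 and 0.04 in oxtr1 females and males (adjusted p = 0.000449, 2 of 17 higher in the male effect; adjusted p = 0.625 with an estimated correlation). Nuclear genes of oxidative phosphorylation had medians of 0.21 and 0.07 (adjusted p = 0.000272, 8 of 43; adjusted p = 0.625 with an estimated correlation). Ribosomal protein genes had medians of 0.06 and -0.01 (adjusted p = 0.00324, 9 of 57; adjusted p = 0.658 with an estimated correlation).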

How the results depend on the processing

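The alternatives were chosen before the data were examined, except 4 added after: the libraries numbered 1 and 2 alone, a term for number 3, genes without shared exon bases, and library sizes without the 10 most counted genes. Over 547 values of named genes called, none changed direction in any alternative: DESeq2 kept 533 calls, a fit of the compared groups alone 492 of 542, the pituitary score 454, the libraries numbered 1 and 2 alone 452, the block and the term for number 3 all 547, and leaving out a library 4073 of 4776. These genes were picked from calls of the main fit and refitted on the same libraries. Their unchanged direction was largely set by that choice and is no independent support. Averaged counts stayed within 1.5 times under all alternatives (2655 to 4667 for oxt, 2161 to 3676 for oxtr1, 2433 to 4321 for both mutants). The cause of the changes below was not tested, except where fewer libraries or genes were used. Depth limits low genes such as itr1.

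With replicate number as a block, calls were 2218 and 1984 for oxt females and males, 2453 for oxtr1 females, and 16, 27 and 11 for sex in wild type, oxt and oxtr1. Shared calls of both mutants with the block were 957 (females) and 385 (males), and of both sexes in oxt 1217. A term for number 3 gave 2214, 1990 and 2466 for the mutants and 19, 26 and 8 for sex. DESeq2 gave 18, 23 and 13 genes for sex and 1 for each difference of effects between sexes. Fits of the compared groups alone gave 687 for oxtr1 males, 18 for sex in wild type and 0 in oxtr1. The pituitary score gave 3 for sex in oxt, 28 in oxtr1, and vasotocin at log2 -0.084 in oxtr1 females (0.07 without it, uncalled). No filter gave 17 for sex in oxt. Genes without shared exon bases gave 6 for sex in oxt, 1 in oxtr1, and 4 chromosomes for oxt males. The libraries numbered 1 and 2 alone gave 9 for sex in oxtr1, 1 for each difference of effects, and 3 and 1 shared sex calls of wild type with oxt and oxtr1. Lists were called 66 times, 9 with an estimated correlation (all 9 among the 66), 57 with fry (42 among them), 67 with the block (63) and 69 with numbers 1 and 2 alone (53).

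At an unadjusted p under 0.01, shared calls of both mutants were 827 (females) and 404 (males; simulated means 22.5 and 23.1), of both sexes in oxt 1107, of sex 34 (wild type and oxt), 15 (wild type and oxtr1) and 13 (oxt and oxtr1), chromosomes 3 for oxt females and 6 for oxtr1 females, and odds ratios near the mutated gene 1.31 for oxt males and 1.07 for averaged oxtr1. A window of 10 Mb gave 1.34, 1.28 and 1.15 for oxt females, males and averaged, and 1 of 2 Mb gave 2.47, 2.36 and 1.82 for these and 1.02 for averaged oxtr1, against 0.978 for the planned window.

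Leaving out a library, counts ran from 650 to 931 (oxt females), 471 to 966 (oxt males), 986 to 1581 (oxtr1 females), 701 to 955 (oxtr1 males), 3 to 8 (sex in wild type), 7 to 11 (sex in oxt), 4 to 10 (sex in oxtr1) and 0 to 4 (difference of the oxtr1 effect). Uncalled log2 changes that turned sign ran in oxt females from -0.171 to 0.255 for oxtr, in oxtr1 females from -0.119 to 0.242 for oxytocin (LOC101160739), -0.108 to 0.236 for LOC101161247 and -0.147 to 0.282 for vasotocin, and in oxtr1 males from -0.417 to 0.279 for vasotocin.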

Other observations

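The tests of neighbouring genes, of both mutants against each other as one pathway, of library depth, of chromosome ends, of the opposite-strand gene and of genes near oxytocin were chosen after the results were seen, as were the comparisons of numbered libraries and the single libraries named here. The tests of overlapping genes, of gene length, of hypothalamic tissue and of other splits were set before.

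The libraries numbered 3 had their own expression profile in every group. Genes of the mitochondrial chromosome were higher in them (23 of 37 called higher and 0 lower, median log2 0.52, adjusted p = 2.49e-16; adjusted p = 0.233 with an estimated correlation), with ATP8 higher by 1.25 and ND6 by 1.11 on the log2 scale. Ribosomal protein genes were lower (2 higher and 17 lower of 57, adjusted p = 0.00555), and neuron genes (4 higher and 1 lower of 17, 0.00441) and stress genes (5 higher and 0 lower of 19, 0.0182) were higher, none of which passed with an estimated correlation (adjusted p = 0.957, 0.748 and 0.398). Of 12 circadian genes 4 were lower, per1, per2, hsf2 and csnk1d (log2 -0.53, -0.43, -0.25 and -0.19), and 0 higher, but the list did not pass (adjusted p = 0.156). In all 3065 genes differed between number 3 and the others (1227 higher, 1838 lower), against 1 between numbers 2 and 1.

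Of the 6 genes with a wild-type sex difference, 3 were irregular in oxtr1 males, f13a1, uso1 and gal. The female-biased f13a1 had 35.6 CPM in oxtr1 male replicate 2, against 4.05 and 1.08 CPM in replicates 1 and 3 and at most 7.85 CPM in any wild-type or oxt male library. The female-biased npb stayed at male levels in the oxtr1 males (2.16 ± 0.226 CPM), and cyp19b fell below them (55.7 ± 7.74 against 76.8 ± 3.92 CPM in wild-type males). The male-biased uso1 on chromosome 1 had 29.8, 36.9 and 26.8 CPM in the 3 oxtr1 male libraries, against 44.4 CPM or more in each wild-type and oxt male library and 22.5 to 27.2 CPM in female libraries. The male-biased gal had 5.06 CPM in oxtr1 male replicate 1, against 16.8 and 12.7 CPM in replicates 2 and 3, at least 9.29 CPM in each wild-type and oxt male library and at most 4.19 CPM in any female library. The female-biased LOC100125524 had 12.7 to 17.8 CPM in oxtr1 males and 18 to 20.2 CPM in oxtr1 females, while in oxt mutants males and females overlapped (24.6 to 27 and 24.8 to 31.1 CPM; adjusted p = 1 for the difference of the oxt effect between the sexes). The mutant effect on uso1 in males passed (log2 -0.67, adjusted p = 0.00122), but the oxtr1 effect did not differ between the sexes at the threshold for uso1, f13a1 or LOC100125524 (adjusted p = 0.672 each) or gal (0.994).

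Between 1103 and 1627 genes differed from wild type in each mutant and sex. Tested directly, 3181 genes differed between both mutants, 1.11 times the smaller count against wild type, so their profiles were not alike. This count cannot decide on 1 oxytocin pathway as the whole cause. A changed peptide and a mutated receptor, with oxtr still transcribed, need not alter that pathway alike. Double counting of reads would put the calls on genes with shared exon bases. The share of genes called among those without shared exon bases was at least 0.98 times the share among all, which argues against it. Variants of each line inherited as chromosome blocks may contribute, since the top 800 genes lay side by side 1.82 times as often as permuted in oxt and 2 times in oxtr1 mutants (permutation p = 0.000999 each, the smallest the permutations can give), and 2.36 times between both mutants, while number 2 against 1 gave 0.883 (permutation p = 0.809). The number 3 effect, which crosses all lines and is itself tied to chromosome ends, gave 2.09, and over all called genes the ratios were lower (1.14 in oxt, 1.42 in oxtr1, 1.38 between both mutants, 1.34 for number 3), so an effect without line variants can reach such values and the blocks cannot be told apart from clustering of another origin. The mutations themselves stay open and cannot be separated from the lines that carry them, and because both mutants were compared with the same wild-type libraries, part of their shared calls may come from those controls.

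The second pattern is the profile of the libraries numbered 3. Library depth as the cause would need number 3 to be lowest or highest in every group, and it was lowest in 4 and between the others in 2. The make-up of the counts did differ in all 6 groups. Number 3 had the lowest share on the 10 most counted genes and the highest on mitochondrial genes in each. What caused this was not tested. Gene length or RNA degradation stays open, since the effect had a weak rank correlation with exon bases (Spearman's rho 0.135, across genes, against 0.0142 for number 2 against 1), and it overlaps with position, as genes near chromosome ends are shorter (median 2229 against 3020 exon bases) and less expressed (median 13.4 against 15.4 CPM). Called genes lay 2.08 times as often within 2 Mb of a chromosome end as elsewhere (29.4% against 14.1%; 67 higher and 703 lower near ends), against 1.02 for oxt and 1.12 for oxtr1 mutants, so a bias tied to gene position, possibly base composition, which no genome sequence was at hand to test, is a candidate explanation. A shared sampling time or preparation day is untested, since the labels give neither.

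The third pattern is the rise of oxytocin transcripts in fish whose oxytocin gene is mutated. Reads of the gene on the opposite strand would lift that gene's own exon bases too, but its count less that of oxytocin moved by -0.035 times the rise of oxytocin, or less, in either sex. More hypothalamic tissue in the mutant samples remains a candidate explanation: with the mean of 25 other neuropeptides as a covariate the log2 change fell from 1.24 (SE 0.16) to 0.505 (SE 0.375, unadjusted p = 0.194), as the change shrank and its error grew, because the covariate itself moves with genotype. That covariate could also follow the mutation, if altered oxytocin changes other peptides. A line variant near the gene cannot be told apart from the mutation that the same fish carry. With the sexes averaged, 4 of the 15 other tested genes within 0.1 Mb were called (LOC101160076, LOC101162133, znf366 and vasotocin, log2 0.20, 1.68, 0.81 and 0.91). These are too few to set apart from the 18.9% of all genes called. Within 2 Mb, oxytocin and LOC101161247 included, 43 of 145 genes were called (29.7% against 18.8% elsewhere, Fisher's exact p = 0.00185). A feedback of altered oxytocin signalling on its gene was not tested.

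Other splits of the samples show how often regrouping gives as many genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) reached the real count for oxt females (1275, highest other 0), oxt males (1133, 0), oxtr1 females (1627, 0), oxtr1 males (1103, 0), sex in wild type (6, 0) and sex in oxt mutants (11, 1). For sex in oxtr1 mutants 4 of 10 splits reached the real 4, and the split of female replicates 1 and 3 and male replicate 3 against the rest gave 114, a structure in these 6 libraries that is much larger than sex, beside which the blocked sex count was 11. That split puts both libraries numbered 3 on the same side. The splits carried no block, although same-numbered libraries moved together in this comparison. With 100 splits drawn, the real split alone (1 of 100, a share under 0.05) reached the real count for the averaged comparisons. These were oxt (3541, highest other 95), oxtr1 (2862, highest other 901) and both mutants (3181, highest other 1170). The other splits put libraries of both genotypes in a group, which widens the fitted spread and lowers their counts, so they do not exclude chance. Nor can they tell a mutation from the line that carries it. For number 3 the real split gave 3065 and the highest other 1, with 100 drawn of 729 possible splits. That grouping was taken up because it stood apart in these same libraries, so its splits are no independent test of chance. For the differences of effects between the sexes the real counts were 0 (edgeR; 432 and 1248 at an unadjusted p under 0.05, 1 each with DESeq2), which all 100 splits reach by definition (highest others 29 for oxt and 220 for oxtr1), so these splits say nothing about chance.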
